A study of Macaca mulatta with 29 samples.

How the data were processed

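RNA was measured in 29 libraries of a rhesus macaque embryonic stem cell line, ORMES-6, kept on mitotically inactivated mouse embryonic fibroblasts in 5% oxygen. Colonies were exposed for 4 weeks to methanol vehicle or to 1 of 5 compounds, in 1 6-well plate per treatment. Per the labels' protocols, 100 ng of RNA per sample was amplified with Ribo-SPIA chemistry and sequenced on an Illumina instrument as 50 nt single-end reads; all colonies of a well were harvested together, about 24 h after the last change of medium. The labels state no batch, day or library pool. Each group was named from the library titles, and all 29 value columns matched 1 title each.

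The deposited table holds FPKM values per gene, which the authors had already scaled for gene length and library size. Per the submitters' processing notes, TopHat2 2.1.1, SAMtools and Cuffdiff 2.2.1 were used, and the genome build GRCm38.p5, a mouse build, is named without its role; the rhesus build is not given in the sources used here. Rows carry human gene symbols and human Entrez identifiers, so a row stands for the human homolog of a macaque gene. No gene coordinates were used here. How reads from the mouse feeder cells were treated is not given in the sources used here.

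Values were log2 transformed after adding 1 FPKM, and genes with a mean of at least 1 FPKM over all libraries were kept, 11080 of 16048. A fold change below is a difference of log2(FPKM + 1), which understates the change of low genes. Group differences were tested with limma 3.58.1 in R 4.3.3 (moderated test with a mean-variance trend, two-sided, all 6 groups in 1 fit), with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Count models were not used, because FPKM are not counts. Each compound was compared with vehicle, the vehicle with the mean of the 5 compounds, and each compound with the mean of the other compounds. The named genes follow a rule: up to 12 higher and 12 lower genes with the largest change among those past the threshold, or, with fewer than 5 calls, all of them and the 5 smallest unadjusted p; up to 4 members of each gene list with the smallest p; 10 genes named beforehand, of which PAX6, T, SOX17 and CDX2 did not pass the filter; and up to 10 genes called in most compounds.

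There were 41 gene lists, and 39 had at least 5 genes past the filter. They were tested with camera at a preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over the 39 lists. Camera with the correlation estimated from the data and fry served as alternatives. At the preset correlation, random splits of the libraries of 1 compound and vehicle also gave called lists, with a median of 4 to 6 per compound. The groups, tests, lists, naming rule and the alternatives named next were set before the data were examined. The alternatives were another pseudocount, 2 other filters, median-of-ratios and quantile scaling, fits on fewer groups, the replicate number as a block, other estimates of the spread, library weights, a feeder covariate and leaving out each library.

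FPKM does not give read counts, but the values of low genes fall on steps, each worth 1 read, and the ratio of the steps gives relative depth. Of 16031 low values in 1741 genes, 97.7% were whole multiples within 0.1 of a step. Depth is given as a percentage of the deepest library. In simulated libraries with known depth the recovered values were off in 0 of 29 libraries, after a first version of the method had misjudged very shallow simulated libraries and was corrected. The simulated values were exact whole steps, so this checks the procedure and not the depths of the real libraries. Absolute depth is unknown.

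The test was run on simulated data for 11080 genes with the spread of each group. For tributyltin against vehicle, 19.1% of simulated changes of 0.3, 78.1% of 0.6 and 97.6% of 1 on the log2 scale were called. For bisphenol A against vehicle these shares were 24.5%, 75.8% and 96.1%, with a mean of 25.8 false calls among the genes left unchanged, against 16.4 for tributyltin, 10.6 for atrazine, 5.8 for PFOA and 2 for DEHP, each with 200 genes changed and 1 list shifted. The median SD of a gene was 0.197 in the bisphenol A libraries, 0.18 with tributyltin, 0.161 with atrazine, 0.138 with PFOA and 0.13 in the DEHP libraries. False calls followed this order, while the test used a spread shared by all groups. The same threshold was thus looser for bisphenol A and tributyltin than for DEHP. Counts of called genes are therefore not strictly comparable between compounds. Only comparisons with vehicle were simulated.

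Nothing in the labels says that the same replicate number in 2 groups marks a shared origin. The deviations of same-numbered libraries from their group means were correlated at over 0.1 in every pair only for tributyltin and vehicle, where the lowest of 5 correlations was 0.175, so for that comparison the fit with the replicate number as a block is given beside the fit without it. The mean correlation was 0.459 there, 0.33 for atrazine, 0.283 for DEHP, 0.161 for PFOA and 0.146 for bisphenol A. Such deviations were thus not particular to tributyltin. The main fit ignores them, and counts with the block are given for the other compounds as well. Wells of 1 plate were the replicates, so p-values measure the spread between wells and not between independently repeated exposures. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.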

Results

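Gene expression was measured in rhesus macaque embryonic stem cells after 4 weeks with 5 endocrine-disrupting compounds, at doses the labels call environmentally relevant, to ask how chronic low exposure acts on these cells. The compounds were atrazine, a herbicide, at 30 uM; bisphenol A, a plastics monomer, at 10 nM; di(2-ethylhexyl) phthalate (DEHP), a plasticizer, at 5 uM; perfluorooctanoic acid (PFOA), a fluorinated surfactant, at 100 nM; and tributyltin, an organotin biocide, at 25 nM. Methanol vehicle, atrazine, bisphenol A, PFOA and tributyltin had 5 libraries each and DEHP had 4. Each treatment was kept in 1 plate, so compound and plate cannot be told apart for any gene. Words such as rose, fell, raised or changed below describe differences between groups of wells. The bisphenol A libraries were the shallowest, at 14.2 to 27.2% of the depth of the deepest library, while the other groups lay between 41.2 and 100%. Pearson correlations of log2 values between libraries of 1 group ran from 0.97 to 0.995 across genes.

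Pluripotency genes were high in every group. POU5F1, the central pluripotency transcription factor, had 523 ± 103 FPKM (SD, n = 5) in vehicle and group means of 489 to 554 FPKM with the compounds. NANOG had 132 ± 8.37 FPKM in vehicle and SOX2 had 124 ± 14.4 FPKM. None of POU5F1, NANOG, SOX2, LIN28A, the DNA methyltransferase DNMT3B or the collagen COL1A1, which fibroblasts express, passed the limma test against vehicle for any compound. Among the first 4 the changes furthest from 0 were those of LIN28A with atrazine, at a log2 fold change of -0.26 (SE 0.11, adjusted p = 0.597), and with PFOA, at -0.18 (adjusted p = 0.956).

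Tributyltin differed from vehicle in the most genes, 22 higher and 116 lower. In simulated data this comparison gave more false calls than those of atrazine, PFOA and DEHP, so the counts are not strictly comparable. ABCA1 (human Entrez 19), which exports cholesterol from cells, rose from 14.4 ± 2.38 to 53.5 ± 3.60 FPKM (SD, n = 5 each), a log2 fold change of 1.84 (SE 0.16, adjusted p = 5.86e-09), higher in 5 of 5 libraries. NODAL (4838) and LEFTY2 (7044), a ligand and an inhibitor of the same signalling pathway, rose by 0.72 (adjusted p = 0.000141) and 0.87 (adjusted p = 0.000277) on the log2 scale. CYP26A1 (1592), which degrades retinoic acid, rose from 5.99 ± 0.943 to 10.6 ± 1.48 FPKM, and the retinoic acid receptor gene RARB (5915) from 1.15 ± 0.383 to 2.33 ± 0.333 FPKM. SLC25A20, the mitochondrial carnitine carrier, rose by 0.83 (adjusted p = 8.78e-05) and ACSL3, which activates long-chain fatty acids, by 0.54 (adjusted p = 0.0014). RNF219, TRIM22, LEPREL1, FAM78B and ARHGAP36 were also higher, with log2 fold changes of 0.54 to 0.86. STC1 (6781), a secreted glycoprotein hormone, fell from 29.3 ± 4.79 to 9.72 ± 1.03 FPKM (log2 fold change -1.49, adjusted p = 2.79e-10), and PFKFB4, a regulator of glycolytic flux, from 12.3 ± 2.36 to 4.73 ± 0.758 FPKM. RIMKLA, CLDN14, MGARP, HERC3, NRN1, FAM162A, TNIP1 and DDX58 were lower, with log2 fold changes from -1.40 to -0.82.

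The glycolysis and hypoxia list fell with tributyltin. Of its 37 measured genes, 9 were lower and 0 higher over all genes tested, and 21 were lower and 1 higher adjusted over the list alone; the camera adjusted p was 1.17e-22, and the adjusted p was 0.00113 with an estimated correlation. EGLN1 (54583), an oxygen sensor that marks hypoxia-inducible factor for degradation, fell by 0.98 (SE 0.10, adjusted p = 1.23e-07) on the log2 scale, from 30.7 ± 4.32 to 14.9 ± 0.976 FPKM. The hexokinase HK2 fell by 0.74, the glucose transporter SLC2A1 fell by 0.79 and the histone demethylase KDM3A fell by 0.70, and P4HA1, P4HA2, BNIP3 and HK1 were also lower. The retinoic acid and HOX list was called higher (adjusted p = 5.5e-05, and adjusted p = 0.178 with an estimated correlation). Its 9 measured genes were CYP26A1, RARB, DHRS3, RARG, RARA, STRA6, RDH10, CRABP1 and CRABP2, with no HOX gene among them. CYP26A1 and RARB passed over all genes, and 4 members passed adjusted over the list alone. Cholesterol biosynthesis was called lower (adjusted p = 3.97e-05, and adjusted p = 0.355 with an estimated correlation), with 23 of 23 fold changes negative, 0 members past the threshold over all genes and 1 adjusted over the list alone. Cell cycle G1/S (adjusted p = 0.00551), immediate early (adjusted p = 0.0221) and one-carbon and amino acid metabolism (adjusted p = 0.0416) were called higher, each with an adjusted p = 0.488 with an estimated correlation; over all genes E2F1 of the G1/S list passed, and adjusted over the list alone 1, 3 and 0 members did. Lists that were not called held other changed genes. PPAR and RXR targets had an adjusted p = 0.0597 (0.0383 by fry), with ABCA1 and SLC25A20 higher, a median log2 fold change of -0.0015 and a mean of 0.12. Core pluripotency had an adjusted p = 0.182, with NODAL and LEFTY2 higher, a median of -0.02 and a mean of 0.08. TGF-beta and BMP signalling (adjusted p = 0.0597) held the same 2 genes, and fatty acid synthesis (adjusted p = 0.325) held ACSL3. Primed pluripotency had an adjusted p = 0.064 (0.0342 by fry) and a median of -0.08, with ETV5 and SPRY4 lower over all genes, at log2 fold changes of -0.43 and -0.36, and 4 members lower adjusted over the list alone. The chromatin list (adjusted p = 0.0584) held KDM5B and KDM4C, lower at -0.32 and -0.40, and interferon response (adjusted p = 0.121) held DDX58. The calls of KDM4C and KDM5B were lost under 13 of 25 alternatives each, that of SPRY4 under 11 of 25, of E2F1 under 10 of 24, of FAM78B under 6 of 24 and of ETV5 under 4 of 25. With the replicate number as a block over all groups, 420 genes were called, 118 higher and 302 lower, among them all 138 of the fit without it. A block in the tributyltin and vehicle libraries alone called fewer genes, as given below. With the block over all groups the glycolysis and hypoxia list had an adjusted p = 1.07e-21, and an adjusted p = 0.0258 with an estimated correlation. The block left the 5 other called lists past the threshold, with adjusted p = 9.46e-05 for cholesterol biosynthesis, 0.000642 for retinoic acid and HOX, 0.0059 for G1/S, and 0.0352 for both immediate early and one-carbon genes. It added lower histone genes (adjusted p = 0.0397, against 0.122 without it) and lower chromatin and DNA methylation genes (adjusted p = 0.0418, against 0.0584). With the block and an estimated correlation none of these 7 was called, the smallest adjusted p being 0.23, and the histone and chromatin lists had 0.834 and 0.613. With library weights 254 genes were called. Without vehicle replicate 2 the count of genes was 71, without vehicle replicate 3 it was 82, without tributyltin replicate 1 it was 90, and on the tributyltin and vehicle libraries alone it was 44, where RARB had an adjusted p = 0.0533. Without wells 1 and 5 it was 71, with LEFTY2 at an adjusted p = 0.0522 and RARB at 0.356, and the count of 6 lists was 12 without vehicle replicate 2 and 10 without tributyltin replicate 5.

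**Figure D1:**
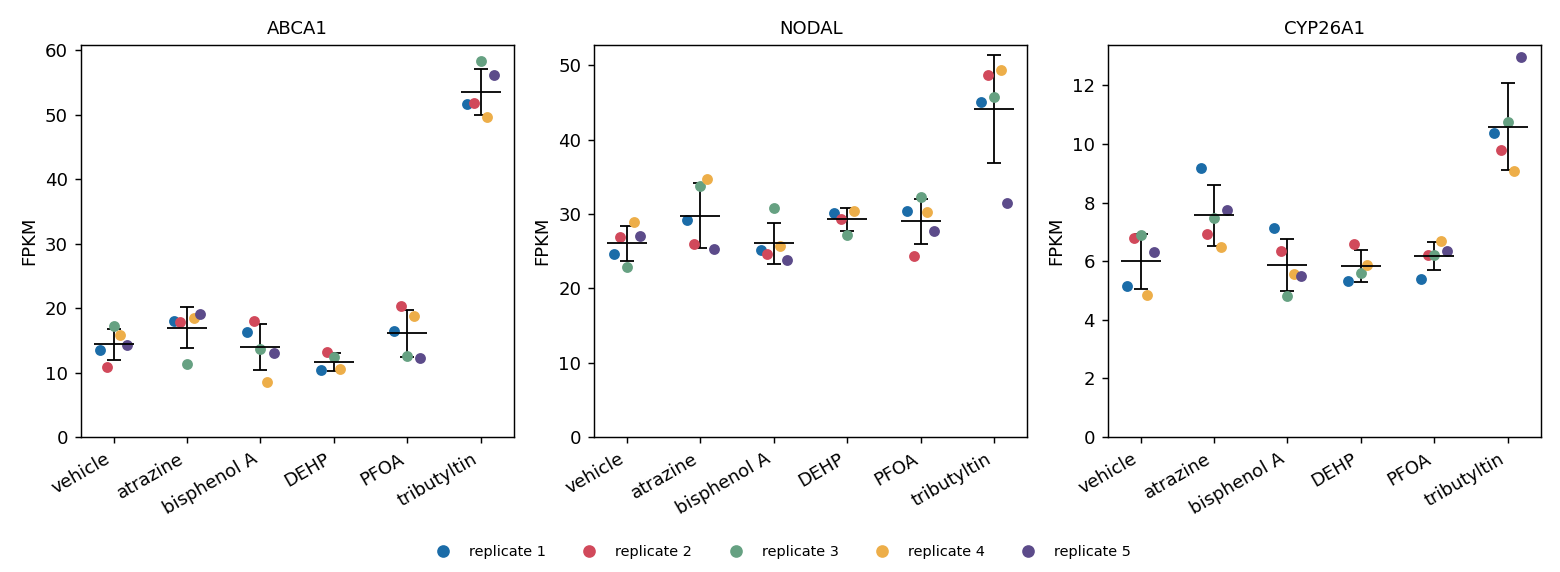
FPKM of ABCA1, NODAL and CYP26A1 in each library, by group; lines give the mean and SD (n = 5, DEHP n = 4) and colours the replicate number. The tributyltin mean of ABCA1 was 53.5 FPKM against 14.4 in vehicle, and NODAL in tributyltin replicate 5, at 31.5 FPKM, was the lowest of its group.

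Atrazine had 21 genes lower than vehicle and 0 higher (limma, with 762 genes at an unadjusted p under 0.05 where 554 are expected by chance). STC1 fell from 29.3 ± 4.79 to 15.7 ± 1.92 FPKM (SD, n = 5 each; log2 fold change -0.85, SE 0.11, adjusted p = 7.52e-05), lower in 5 of 5 libraries. RIMKLA fell by 0.98 (adjusted p = 1.85e-06), CLDN14, a tight junction protein, fell by 0.99 and NRN1 fell by 0.77 on the log2 scale. SAP30, UPRT and the adenylate kinase AK4 had log2 fold changes of -0.63, -0.58 and -0.54. The glycolysis and hypoxia list fell (adjusted p = 5.21e-13, and adjusted p = 0.0259 with an estimated correlation), with EGLN1, SLC2A1, HK2, PFKFB4 and KDM3A lower over all genes and 13 lower adjusted over the list alone. EGLN1 fell from 30.7 ± 4.32 to 18 ± 1.85 FPKM and SLC2A1 from 271 ± 32.1 to 171 ± 20.8 FPKM. Camera called 10 further lists: lower cholesterol biosynthesis, cell cycle G2/M, oxidative phosphorylation, histone and chromatin genes, and higher mesoderm, fibroblast and feeder, immediate early, TGF-beta, and thyroid and glucocorticoid genes. With an estimated correlation none of these 10 was called, the smallest adjusted p being 0.0757; 0 of their members passed over all genes, and at most 3 in any list adjusted over the list alone. The fibroblast and feeder list had an adjusted p = 0.0443, and an adjusted p = 0.493 with an estimated correlation, and the median of its genes averaged 4.47 ± 0.109 log2 units with atrazine and 4.31 ± 0.0672 in vehicle. Without vehicle replicate 2 the count of genes was 12, without atrazine replicate 4 it was 13, and on the atrazine and vehicle libraries alone it was 6; it was 32 with library weights and 84 with the replicate number as a block. Of 24 alternatives, UPRT lost its call under 11 and KDM3A under 5. The count of 11 lists was 7 without atrazine replicate 1 and 7 without atrazine replicate 3.

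PFOA had 18 genes lower than vehicle and 0 higher (limma, with 641 genes at an unadjusted p under 0.05). STC1 fell from 29.3 ± 4.79 to 15.2 ± 1.98 FPKM (SD, n = 5 each; log2 fold change -0.90, SE 0.11, adjusted p = 2.81e-05), lower in 5 of 5 libraries. EGLN1 fell from 30.7 ± 4.32 to 17.4 ± 2.33 FPKM and HK2 from 62.9 ± 4.78 to 43.1 ± 1.65 FPKM. RIMKLA, NRN1, CLDN14, SLC2A1, PTPRB, BHLHE40, PFKFB4, KDM3A and RAB2B had log2 fold changes from -0.88 to -0.49. The call of PTPRB was lost under 13 of 23 alternatives and that of CLDN14 under 10 of 23, and of 24 alternatives RAB2B lost its call under 11, BHLHE40 under 10, KDM3A under 8 and PFKFB4 under 4. In the glycolysis and hypoxia list EGLN1, SLC2A1, PFKFB4, HK2 and KDM3A were lower over all genes and 9 were lower adjusted over the list alone (camera adjusted p = 9.02e-12, and adjusted p = 0.0415 with an estimated correlation). Camera also called lower cholesterol biosynthesis, fatty acid synthesis, WNT signalling and chromatin genes and higher ribosomal protein and immediate early genes. With an estimated correlation none of these 6 was called, the smallest adjusted p being 0.261; 0 members passed over all genes, and adjusted over the list alone 3 chromatin genes were lower. PPAR and RXR targets were not called (adjusted p = 0.914; median log2 fold change 0.0093, mean -0.0075). The count of genes was 7 without vehicle replicate 2, 9 without vehicle replicate 3, 11, 8, 9 and 11 without PFOA replicates 1, 2, 4 and 5 in that order, and 8 on the PFOA and vehicle libraries alone. It was 29 with the feeder covariate, 54 with library weights and 63 with the replicate number as a block.

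DEHP had 1 gene lower than vehicle, STC1, at 18 ± 1.62 FPKM (SD, n = 4) against 29.3 ± 4.79 (SD, n = 5). Its log2 fold change was -0.66 (SE 0.12, adjusted p = 0.0448 by limma), and it was lower in 4 of 4 libraries. The count of higher genes was 0, with 879 genes at an unadjusted p under 0.05. The genes with the next smallest p did not pass, each with an adjusted p = 0.0885. HK2 had 46.5 ± 1.98 FPKM against 62.9 ± 4.78 in vehicle, SPP1, a secreted matrix protein, 20.4 ± 5.26 against 45.2 ± 9.89, BHLHE40 4.81 ± 0.63 against 7.75 ± 1.41, RIOK3 28.3 ± 1.45 against 36 ± 2.88 and IGFBP5 2.33 ± 0.406 against 4.22 ± 0.755. The glycolysis and hypoxia list was called lower (adjusted p = 0.00165, and adjusted p = 0.439 with an estimated correlation); 0 members passed over all genes, and 6 were lower and 1 higher adjusted over the list alone. After quantile normalization that list had an adjusted p = 0.0714. Lower cholesterol biosynthesis, fatty acid synthesis, cell cycle G1/S and chromatin genes and higher xenobiotic metabolism genes were also called; with an estimated correlation none was, the smallest adjusted p being 0.247, and 0 members passed over all genes and 1 chromatin gene adjusted over the list alone. The median of the feeder list averaged 4.44 ± 0.0814 log2 units with DEHP. The call of STC1 was lost under 14 of 23 alternatives, among them leaving out any of the 4 DEHP libraries or vehicle replicate 1, 2 or 3, each of which gave 0 genes, and 2 genes were called without vehicle replicate 4. Other alternatives raised the count: it was 74 with library weights, 11 higher and 63 lower, 30 with the replicate number as a block, 1 higher and 29 lower, 4 without a filter, 3 without the bisphenol A libraries and 2 with the depth covariate. The number of genes called with DEHP thus depends on the fit. The count of 6 lists was 3 without DEHP replicate 2.

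Bisphenol A differed from vehicle in 0 genes by limma, with 573 genes at an unadjusted p under 0.05 where 554 are expected by chance. The genes with the smallest p did not pass. CYP3A5, a drug-metabolizing cytochrome, had 3.07 ± 0.325 FPKM against 1.75 ± 0.18 in vehicle (SD, n = 5 each; adjusted p = 0.121 by limma), SLC6A11, a GABA transporter, 2.21 ± 0.458 against 3.95 ± 0.631, and TXNIP 58.6 ± 8.32 against 43 ± 4.57; GTSF1 and TCEAL5 had log2 fold changes of -0.74 and -0.62 (adjusted p = 0.343). The glycolysis and hypoxia list was not called (adjusted p = 0.534). Camera called 8 lists: higher endoderm, fibroblast and feeder, immediate early and extracellular matrix genes, and lower cell cycle G1/S, oxidative phosphorylation, ribosomal protein and histone genes. With an estimated correlation none was called, the smallest adjusted p being 0.317. Over all genes 0 members passed, and adjusted over the list alone 5 immediate early genes were higher and 4 histone genes lower. Random splits of the bisphenol A and vehicle libraries alone gave a median of 4 called lists. The bisphenol A libraries had 14.2 to 27.2% of the depth of the deepest library and those of vehicle 47.7 to 100%. Compound and depth cannot be separated in this comparison either. Androgen and estrogen receptor targets were not called (adjusted p = 0.534). The 95% interval of the median gene reached 0.229 log2 units to either side of its fold change. This width rests on the spread shared by all groups and was the same for atrazine, PFOA and tributyltin. The median SD of a gene was largest in the bisphenol A libraries, at 0.197, so the width may understate the uncertainty here. With the replicate number as a block the count of genes was 3, and without a filter it was 1. Without bisphenol A replicate 2 the count of genes was 1 and that of lists 5, and without vehicle replicate 5 that of lists was 4.

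Several genes were lower with more than 1 compound. STC1 was called lower with 4 compounds, and 13 genes with 3, among them CLDN14, RIMKLA, EGLN1, NRN1, PFKFB4, HK2, SLC2A1, KDM3A and AK4. Some of these calls depended on the fit: STC1 with DEHP was lost under 14 of 23 alternatives, and with PFOA CLDN14 was lost under 10 of 23, AK4 under 10 of 24 and KDM3A under 8 of 24. Atrazine and PFOA shared 14 lower genes where independent lists of their sizes would share 0.0341, atrazine and tributyltin shared 19, and PFOA and tributyltin shared 18. These comparisons share their vehicle libraries. In 100 simulated sets of unchanged groups with shared controls, 96 had 0 genes called in at least 2 comparisons, and 2 had as many as the observed 23, the highest being 809. These sets moved the deviations of wells freely between groups, so they held no differences between plates. They cannot tell whether a vehicle plate that stood apart gave the shared calls. Over the 10 pairs of compounds the median Pearson correlation of fold changes across genes, which are not independent replicates, was 0.47. It was 0.49 for unchanged groups that share controls and 0.0251 when the vehicle libraries were split between the compounds.

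**Figure D2:**
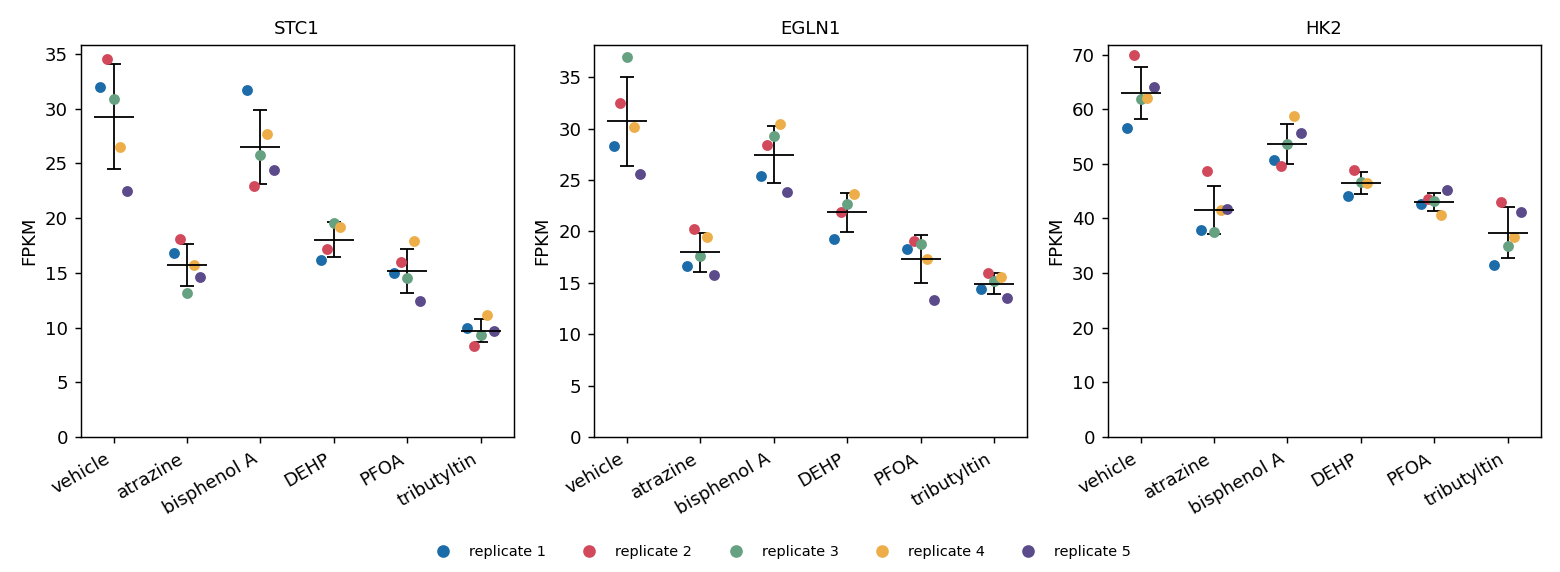
FPKM of STC1, EGLN1 and HK2 in each library, by group; lines give the mean and SD (n = 5, DEHP n = 4) and colours the replicate number. Vehicle means were 29.3, 30.7 and 62.9 FPKM, and tributyltin means of STC1 and EGLN1 were 9.72 and 14.9 FPKM.

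Vehicle differed from the mean of the 5 compounds in 28 genes, all higher in vehicle. This comparison averages the 5 comparisons with vehicle above. It cannot tell a vehicle plate that stands apart from a response shared by several compounds. STC1 was higher in vehicle by 0.80 on the log2 scale (adjusted p = 1.39e-06), and EGLN1, PFKFB4, HK2, SLC2A1 and KDM3A of the glycolysis and hypoxia list by 0.63, 0.53, 0.50, 0.50 and 0.47. That list was higher in vehicle (adjusted p = 5.49e-14, and adjusted p = 0.0181 with an estimated correlation), with 5 members over all genes and 12 adjusted over the list alone. The mean log2 value of its 37 genes was 6.10 ± 0.11 in vehicle, 6.07 ± 0.08 with bisphenol A, 5.99 ± 0.07 with DEHP, 5.91 ± 0.04 with PFOA, 5.90 ± 0.05 with atrazine and 5.75 ± 0.08 with tributyltin (SD). Exact permutation tests on these means against vehicle, each of them 2-sided, gave p = 0.00794 for atrazine, PFOA and tributyltin, the smallest this design allows (adjusted p = 0.0132 over 5 tests), p = 0.111 for DEHP (adjusted p = 0.139) and p = 0.651 for bisphenol A. The count of 28 genes was 13 without vehicle replicate 2, 14 without vehicle replicate 3, 74 without the bisphenol A libraries, 14 with relative depth as a covariate, 47 with library weights and 104 with the replicate number as a block.

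**Figure D3:**
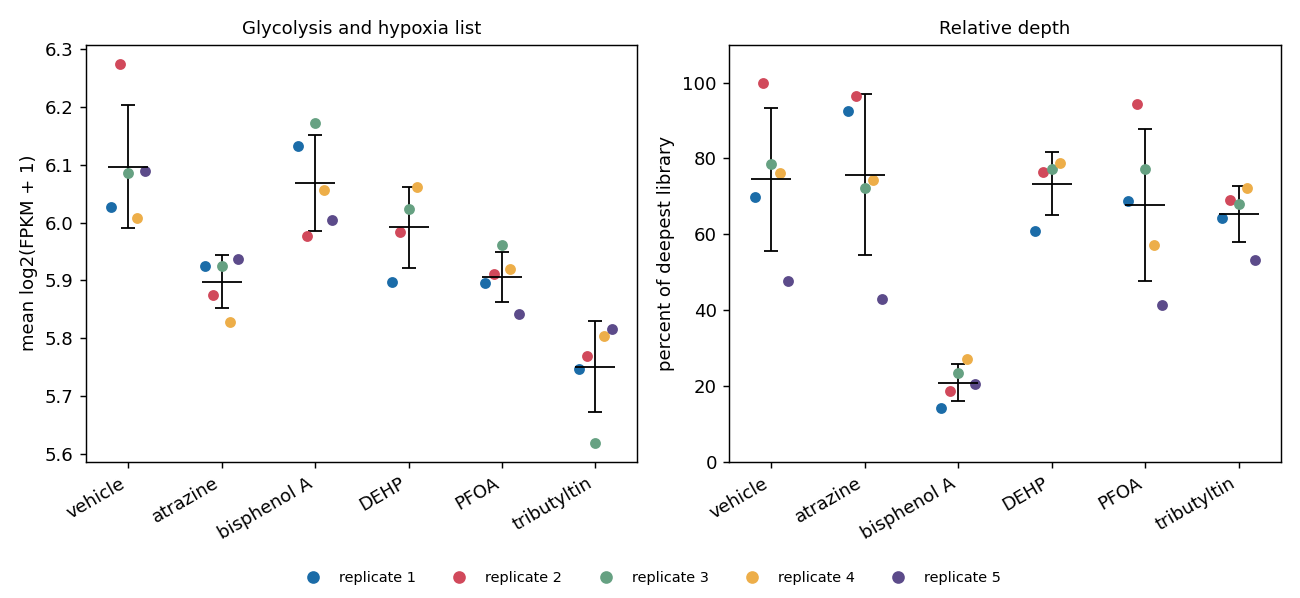
Left, mean log2(FPKM + 1) of the 37 measured glycolysis and hypoxia genes in each library; right, depth of each library as a percentage of the deepest. Lines give the mean and SD per group (n = 5, DEHP n = 4) and colours the replicate number; the bisphenol A libraries had 14.2 to 27.2% of the depth and a list mean of 6.07, against 6.10 in vehicle.

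Each compound was also compared with the mean of the other compounds. The vehicle means did not enter this comparison, but the vehicle libraries entered the shared estimate of the spread. ADM, PDE8A and the direct differences of ABCA1 below were chosen after their values were seen. Tributyltin differed in 215 genes, 78 higher and 137 lower. ABCA1 was higher by 1.83 (adjusted p = 9.12e-11), SLC25A20 by 0.84, CYP26A1 by 0.66 and DNMT3B by 0.37 (adjusted p = 0.004), and STC1 fell by 0.85 (adjusted p = 4.16e-07). The glycolysis and hypoxia list was lower, with 8 members over all genes and 16 lower and 1 higher adjusted over the list alone (adjusted p = 1.09e-12, and adjusted p = 0.0292 with an estimated correlation). The mean of the other compounds included bisphenol A, where the list lay near vehicle. Directly by limma, EGLN1 and HK2 did not pass between tributyltin and atrazine (adjusted p = 0.37 and 0.592) or PFOA (adjusted p = 0.807 and 0.624). Against bisphenol A both passed, and against DEHP only EGLN1 did (adjusted p = 0.0115, HK2 0.112). STC1 passed directly against each compound. Bisphenol A differed in 126 genes, 73 higher and 53 lower. The mean of the other compounds included tributyltin, from which bisphenol A differed directly in 277 genes, against 30 for PFOA, 15 for atrazine and 6 for DEHP. Directly against DEHP, STC1 did not pass (limma adjusted p = 0.0921). The bisphenol A libraries had 14.2 to 27.2% of the depth of the deepest library and those of the other compounds 41.2 to 96.5%, so in this comparison, its list included, compound and depth cannot be separated. STC1 was higher by 0.84 (adjusted p = 1.68e-06), ADM, a vasodilator peptide, by 0.87, BHLHE40 by 0.76 and EGLN1 by 0.59. The glycolysis and hypoxia list was higher with bisphenol A, with 7 members over all genes and 9 adjusted over the list alone (adjusted p = 1.05e-11, and adjusted p = 0.0426 with an estimated correlation). Atrazine differed in 1 gene, the phosphodiesterase PDE8A, higher by 0.56 (adjusted p = 0.0218), DEHP in 1, ABCA1, at a log2 fold change of -0.81 (adjusted p = 0.0211), and PFOA in 0 by limma, with 497 genes at an unadjusted p under 0.05. The mean for DEHP included tributyltin, which raised ABCA1: directly, DEHP differed from tributyltin by -2.12 (adjusted p = 3.31e-09) and from PFOA by -0.42 (adjusted p = 0.999), and ABCA1 was higher than with DEHP by 0.50 with atrazine (adjusted p = 1) and by 0.21 with bisphenol A (adjusted p = 0.825). The tributyltin count was 103, 92, 116 and 76 without tributyltin replicates 1, 2, 4 and 5 in that order. The bisphenol A count was 50 without bisphenol A replicate 2 and 30 with library weights. With the replicate number as a block the counts were 529 for tributyltin, 543 for bisphenol A, 19 for atrazine and 3 for DEHP, and library weights gave 453 for tributyltin, 28 for atrazine and 15 for DEHP. The atrazine count was 0 without any 1 of atrazine replicates 1 to 4, 5 without atrazine replicate 5, 2, 4 and 5 without bisphenol A replicates 1, 3 and 4 in that order, and 4 without tributyltin replicate 3. The DEHP count was 0 without any 1 of its 4 libraries and 2 without bisphenol A replicate 3.

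Compounds were compared directly as well. Tributyltin differed from bisphenol A in 277 genes, from atrazine in 107, from DEHP in 53 and from PFOA in 18. ABCA1 was lower with atrazine than with tributyltin, at a log2 fold change of -1.62 (SE 0.16, adjusted p = 4.41e-07), as was NODAL, at -0.54 (adjusted p = 0.00658). STC1 was higher with bisphenol A than with tributyltin by 1.36 (adjusted p = 5.21e-09) and than with PFOA by 0.77 (adjusted p = 0.000582). Bisphenol A differed from PFOA in 30 genes, from atrazine in 15 and from DEHP in 6. In these counts and in the 277 genes above, compound and depth cannot be separated either. Atrazine and DEHP, atrazine and PFOA, and DEHP and PFOA differed in 0 genes by limma, with 257, 376 and 420 genes at an unadjusted p under 0.05. The 95% interval of STC1 for atrazine minus PFOA ran from -0.17 to 0.27, and these counts of 0 do not show that the compounds act alike. Direct comparisons between compounds were not run with the replicate number as a block.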

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

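The tests of the vehicle plate, of culture differences between plates, of low depth with bisphenol A and of shared handling of wells were chosen only after the result was seen. The others in this part were not, although the interval for the depth test on the glycolysis and hypoxia genes was computed with another method after a first run.

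In 13 of 187 groups of values, 6.95% where chance gives about 5%, 1 library lay far from the rest of its group. DEHP replicate 1 had a relative depth of 61%, against 76.4 to 78.7% in the other DEHP libraries, 14137 genes above 0 against 14271 to 14294, and 501 FPKM of POU5F1 against 549 to 555. Vehicle replicate 5 had 13872 genes above 0 against 14222 to 14356, 4.22 FPKM of PTPRB against 5.52 to 6, and 4.71 FPKM of RIMKLA against 6.6 to 7.26. Vehicle replicate 2 had 10.2 FPKM of BHLHE40 against 6.92 to 7.5. Bisphenol A replicate 1 had 13196 genes above 0 against 13447 to 13549. Bisphenol A replicate 4 had 126 FPKM of AK4 against 105 to 109, and 0.872 FPKM of CLDN14 against 2.09 to 2.53. Tributyltin replicate 1 had 17.4% of its FPKM in its top 20 genes against 14.7 to 15.2%, and 13.6 FPKM of KDM3A against 17.8 to 18.8. NODAL in tributyltin replicate 5 was at 31.5 FPKM against 45.1 to 49.4.

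Glycolysis and hypoxia genes had a lower mean than vehicle with atrazine, PFOA, tributyltin and DEHP, the last not past its test. A vehicle plate that alone stood apart was argued against as the whole cause for tributyltin, where the list mean differed by -0.176 from atrazine, DEHP and PFOA, at overlapping depths (exact permutation p = 8.6e-05, the smallest this test can give). For atrazine, DEHP and PFOA it cannot be told apart from the compounds: bisphenol A was 0.141 higher than these (exact permutation p = 0.00181), but its depths do not overlap theirs. Depth was argued against as the whole cause: without bisphenol A the difference of the 4 compounds from vehicle was -0.216, and -0.212 after the slope on depth was removed, with an upper 95% bound of -0.106. Culture differences between plates, such as density or oxygen at harvest, cannot be told apart from an effect of the compounds, which stays open, because each treatment was kept in 1 plate (SD of the 6 group means 0.128, of wells within a plate 0.0742).

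Bisphenol A gave 0 calls against vehicle with the shallowest libraries. The same libraries differed from the mean of the other compounds in 126 genes, but at depths of 14.2 to 27.2% against 41.2 to 96.5% of the deepest library, so these calls do not separate compound from depth. In simulated data with the spread of these libraries 75.8% of changes of 0.6 log2 units were called, which excludes nothing for the real ones. Tributyltin exceeded bisphenol A in ABCA1 by 1.90, in NODAL by 0.73 and in CYP26A1 by 0.75 log2 units (limma adjusted p = 5.21e-09, 0.000177 and 5.83e-05). It exceeded vehicle by 1.84, 0.72 and 0.73. These genes were chosen after their values were seen. Each SE came from the spread shared by all groups and was the same against bisphenol A as against vehicle, at 0.157, 0.107 and 0.104. The depth of the bisphenol A libraries thus hardly entered these p-values. The values show only that large differences in these genes were of similar size against both groups. They cannot decide whether depth was too low for calls in other genes or for smaller changes. Low depth cannot be told apart from a small response to bisphenol A or none.

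Libraries with the same replicate number deviated together from their group means, with a mean correlation across genes of 0.287 against -0.0691 for other numbers, and 22 of 29 libraries were closest to their own number. Depth was argued against as the whole cause: with depth removed the mean was 0.199, above the highest of 10000 shuffles of the numbers, 0.153. Shared handling of same-numbered wells cannot be told apart from other sources, because the labels give no handling per well. No biological explanation was tested.

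Other splits of the same libraries were counted for each comparison, 100 each, the real one included. Genes against vehicle were counted on the libraries of 1 compound and vehicle alone. There, 2 splits gave as many calls as the real one for atrazine (6 genes, highest other split 1380). The same held for PFOA (8, highest other 52) and for tributyltin (44, highest other 804). These are not the counts of 21, 18 and 138 from the fit on all groups. Few random groupings of these wells thus gave as many calls. The splits exchange wells freely, although same-numbered wells deviated together, and each group was 1 plate. They cannot exclude chance differences between plates. For bisphenol A (0 genes, highest other 418) and DEHP (0, highest other 267) all 100 gave as many, as a count of 0 always must, so these splits test nothing. The splits with 1380, 418 and 804 genes put wells 1 and 5 of both groups together with vehicle replicate 2, and that with 267 put DEHP replicate 1 with vehicle replicates 1, 2 and 5, a structure of the samples by well number. Of the 16 splits that part all 5 same-numbered pairs of tributyltin and vehicle, 1 gave as many as the real 44 and the highest other gave 0, which is too few splits for a share under 0.05. For lists, 4 splits gave as many as atrazine (11 lists, highest other 12), while 13 did for bisphenol A (9, highest other 14), 22 for DEHP (7, highest other 12), 31 for PFOA (7, highest other 13) and 32 for tributyltin (7, highest other 11), and for these 4 chance cannot be excluded. The median count of lists in the other splits was 5 for atrazine, 4 for bisphenol A, 4 for DEHP, 5 for PFOA and 6 for tributyltin. A typical random grouping thus also gave several called lists. Against the other compounds, 2 of 100 shuffles gave as many for tributyltin (215 genes, highest other 665). For atrazine 5 did (1 gene, highest other 104), so chance cannot be excluded there. For bisphenol A (126 genes, highest other 733) and for DEHP (1 gene, highest other 13) 4 shuffles gave as many. For PFOA (100, 0 genes, highest other 2) the count of 0 again tests nothing. For vehicle against the mean of the compounds 4 shuffles gave as many as 28 (highest other 387). The 4 results with 4 of 100 passed 0.05 by only 1 split. Like the results with 2 of 100, they do not exclude chance differences between plates. All 4 also depended on single libraries: the atrazine lists fell to 7 without atrazine replicate 1 or 3 (and to 1 with an estimated correlation), the bisphenol A genes to 50 without bisphenol A replicate 2, the DEHP gene was lost without any 1 of its 4 libraries, and the vehicle count was 13 without vehicle replicate 2 and 14 without vehicle replicate 3.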

How the results depend on the processing

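The fits without the bisphenol A libraries, without the wells numbered 1 and 5, with relative depth as a covariate and with a block in the tributyltin and vehicle libraries alone, and leaving out libraries in the comparisons with the other compounds and of vehicle with all compounds, were chosen only after the result was seen. Of the values of named genes under the alternatives, 0 turned from a call in 1 direction to the other, 19183 kept their direction and side of the threshold or were called in neither setting (175 of these with another sign), 179 lost their call and 148 gained one. Most of these values were of genes not called in the main fit, which had no call to lose, so the 179 are not a share of all values. ABCA1, NODAL, CYP26A1, SLC25A20 and, with atrazine, PFOA and tributyltin, STC1 kept their calls in each alternative run. The count for PFOA against the mean of the other compounds was 0 in each. The fit on the compound and vehicle libraries was not run for the comparisons that use all groups. Apart from alternatives that test fewer genes or use fewer libraries, the cause of the changes below was not tested.

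Counts of genes against vehicle (21 for atrazine, 0 for bisphenol A, 1 for DEHP, 18 for PFOA, 138 for tributyltin) moved as follows. DEHP gave 0 with a pseudocount of 0.1 FPKM, with median-of-ratios scaling, with quantile normalization, on its own and the vehicle libraries, without a trend, with the feeder covariate and without wells 1 and 5; it gave 4 without a filter, 3 without the bisphenol A libraries and 2 with the depth covariate. Bisphenol A gave 1 without a filter. On the compound and vehicle libraries alone atrazine gave 6, PFOA 8 and tributyltin 44. With the replicate block atrazine gave 84, bisphenol A 3, DEHP 30, PFOA 63 and tributyltin 420, and with the block in the tributyltin and vehicle libraries alone tributyltin gave 271. With library weights atrazine gave 32, DEHP 74, PFOA 54 and tributyltin 254. PFOA gave 29 with the feeder covariate and tributyltin 71 without wells 1 and 5. Leaving out 1 library gave 12 to 22 for atrazine, 0 to 1 for bisphenol A, 0 to 2 for DEHP, 7 to 24 for PFOA and 71 to 156 for tributyltin.

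Counts of lists (11, 8, 6, 7 and 6 in that order) were 1, 0, 0, 1 and 1 with an estimated correlation. Fry gave 4 for atrazine, 0 for bisphenol A, 1 for DEHP, 1 for PFOA and 4 for tributyltin, where PPAR and RXR targets and primed pluripotency were called by fry and not by camera. Atrazine gave 7 with a mean of at least 5 FPKM, DEHP 1 after quantile normalization and bisphenol A 4 with the depth covariate. Leaving out 1 library gave 7 to 12 for atrazine, 4 to 10 for bisphenol A, 3 to 8 for DEHP, 6 to 8 for PFOA and 5 to 12 for tributyltin.

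Vehicle against the mean of the compounds (28) gave 104 with the block, 47 with library weights, 74 without the bisphenol A libraries, 14 with the depth covariate and 13 to 33 leaving out 1 library. Against the other compounds, atrazine (1) gave 0 without a filter, 0 with a mean of at least 5 FPKM, 0 after quantile normalization, 19 with the block, 28 with library weights, 13 without the bisphenol A libraries and 0 to 5 leaving out 1 library. Bisphenol A (126) gave 83 with a mean of at least 5 FPKM, 543 with the block, 30 with library weights and 50 to 156 leaving out 1 library. DEHP (1) gave 2 without a filter, 3 with the block, 15 with library weights, 5 without the bisphenol A libraries and 0 to 2 leaving out 1 library. Tributyltin (215) gave 136 with a mean of at least 5 FPKM, 529 with the block, 453 with library weights and 76 to 256 leaving out 1 library. The median correlation of fold changes between compounds (0.47) was 0.0251 with the vehicle libraries split. Depth is known only relative to the deepest library, so no limit from counts can be given for genes at 0.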

Other observations

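The test in this part was chosen only after the result was seen. With tributyltin, members of the lists of PPAR and RXR targets and of retinoic acid receptors and their targets were looked at together, after ABCA1, CYP26A1, SLC25A20 and RARB had been seen to be higher. Of 33 such genes 4 were higher, against 18 of the other 11047 genes tested (Fisher's exact test, 1-sided, p = 4.59e-07). DHRS3, a retinal reductase, had a log2 fold change of 0.43 (adjusted p = 0.191 by limma) and LPCAT3, a phospholipid-remodelling enzyme, one of 0.18 (adjusted p = 0.492). Of the 33, 14 had a negative fold change, among them PPARD at -0.18 (adjusted p = 0.446), ACADM at -0.24 (adjusted p = 0.589) and STRA6 at -0.20 (adjusted p = 0.709). Tributyltin is known as a ligand of RXR, so a candidate explanation is that it acted through RXR and its partner receptors in these cells; genes are not independent of each other, the genes were found and tested on the same data, and most of the 33 did not pass, so this stays a hypothesis.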
